A study of Mus musculus with 6 samples.

How the data were processed

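Whole testes of 3 control and 3 Rnu11 cKO mice at postnatal day 14 were sequenced as rRNA-depleted, stranded total RNA libraries, per the labels' protocols. The genotype and the replicate number of each library were taken from the labels. The series' design text speaks of animals, so each library was taken as 1 animal. Reads were aligned with HISAT2 to GRCm38, per the submitters' processing notes; the quantification tool, its version, its annotation release and the Cre line of the deletion are not given in the sources used here. The authors deposited TPM estimates per gene and per isoform for each library, with no counts. TPM keeps no depth, so no counting interval or detection floor is given, and a value of 0 can be a failed estimate: such genes are described as listed at 0, with the value of each library. Per the file headers, 2 tables of the whole series hold the authors' average TPM of each group and log2 fold changes, of which the gene table was used for description only. Its group averages equal the means of the 3 libraries. Abundant short RNAs take a large part of each TPM total, so a change in them rescales every other gene of that library.

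Genes with a mean of at least 1 TPM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) on log2(TPM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on this scale and understate the change of genes near 1 TPM. Isoforms were tested in the same way. Isoform shares were tested as log2 of an isoform's TPM plus 0.1 over the TPM of the gene's other isoforms plus 0.1, without trend, for genes of at least 5 TPM and isoforms with 5% to 95% of their gene. Adjusted p-values in all parts come from these limma fits or, for gene lists, from limma's camera with a preset correlation of 0.01, adjusted over lists; camera with an estimated correlation and fry were run beside it. Each of the 23 lists had been written from general knowledge of testis cell types and of the minor spliceosome before the data were examined, and 21 had at least 3 tested members. Counts "over the list alone" use the adjustment within that list. With 3 libraries against 3, an exact permutation test cannot give a p under 0.1, so p-values rest on the spread pooled across genes.

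Gene symbols were matched to GENCODE M21 and RefSeq symbols (54452 of 55353), and 141524 of 142647 isoforms to GENCODE M21. Without a genome sequence, intron bases were read from GENCODE M21 transcripts that cover them, which covered 20892 of 250739 introns of protein-coding genes. A minor intron was one of at least 60 nt that starts with G or A and then TATCCTT, with at most 1 mismatch among the last 6 of these 8 bases, ends in AG or AC, and has a TCCTTRA branch site (R is A or G) with at most 1 mismatch and its last A 8 to 30 nt from the intron's end. This gave 86 introns in 82 genes. Because most introns could not be read, the gene-level set was the hand-written list of 60 genes, 9 of which have such an intron among those read. The ratio of each intron was log2 of the TPM of isoforms that splice it plus 0.1 over the TPM of isoforms that span it without splicing it exactly plus 0.1, for introns where both sums averaged at least 0.5 TPM.

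Genes are named by a rule fixed beforehand. It takes Rnu11 and other minor spliceosome snRNAs; among protein-coding genes called, with at least 5 TPM and no overlap of groups, the 12 most positive and the 12 most negative (with fewer than 5 such genes, the 10 with the smallest p-value); up to 4 genes per list by p-value; 6 higher and 6 lower minor intron genes; the 5 isoforms, shares and minor introns with the smallest p-value; and up to 3 called noncoding genes in each direction. Genes beyond these were named after their values were seen. These are Spo11, the remaining called minor introns in E2f6 and Ssr3, the second Prim1 intron, other E2F genes of the hand-written list, the called gene Gm25556, the called isoform of Gm22042, and the introns of Rnpc3, Snrnp48, Ccdc84, Derl2, Rmc1 and Pfdn6. Prm1 and Tnp1 were also named in this way.

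Alternatives were another pseudocount, no filter or a filter of 5 TPM, median-ratio scaling, TPM rescaled over nuclear protein-coding genes, no trend, a replicate block, each library left out in turn, other definitions of minor introns, and an estimated correlation. On simulated data with the spread of these libraries, the gene fit recovered 61% of genes changed by 1 log2 unit and 93% of those changed by 2, over 17959 genes, and the isoform fit 34% and 61% over 44197 isoforms. Camera called a list of 30 genes shifted by −0.4 in 50 of 50 draws and an unshifted list in 0 of 50; these simulated genes were independent of each other. Other steps used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.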

Results

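RNA was profiled in whole testes of mice at postnatal day 14, with 3 control animals and 3 animals carrying a conditional deletion of Rnu11 (Rnu11 cKO, called mutants here). Rnu11 encodes U11, a small nuclear RNA of the minor spliceosome, which removes a rare class of introns with splice sites of their own. At this age the first wave of spermatogenesis has reached meiotic prophase. Spermatid genes such as Prm1 and Tnp1 were under 1 TPM in every library. The libraries were made from total RNA depleted of ribosomal RNA, and each gave a TPM value for 55353 genes and 142647 isoforms. Between 30113 and 34510 genes per library were above 0. TPM keeps no record of sequencing depth, so the depth behind each value is unknown. The short RNA gene Rn7s2 took 26.9% to 30.5% of the TPM of a library, Rn7sk took 12.3% to 15.2%, and protein-coding genes of the nuclear genome took 27.1% to 32.2%. Across genes, which are not independent replicates, log2 values correlated at 0.953 to 0.956 between controls, 0.954 to 0.960 between mutants and 0.934 to 0.968 between the groups. The cells in which Rnu11 was deleted are not given in the sources used here. The comparison addresses what loss of U11 does to minor splicing and to spermatogenesis.

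The deleted gene was lower in every mutant library than in every control. Rnu11 (ENSMUSG00000077323.1, GRCm38 chromosome 4, 132270080 to 132270213, annotated as an snRNA gene) stood at 580.4 ± 32.3 TPM in controls (SD, n = 3) and at 264 ± 112 TPM in mutants (SD, n = 3). The mutant libraries read 196, 393 and 203 TPM against 614, 576 and 550.3 TPM in controls. The log2 difference was −1.21 (SE 0.26), a 2.31-fold lower level in mutants, and it missed the threshold over all genes (limma, adjusted p = 0.29). Without mutant replicate 2, the mutant library with the highest level, it was −1.53 and passed (limma, adjusted p = 0.037). Over the alternatives recorded for Rnu11, the limma adjusted p ran from 0.037 to 0.60. Those with no filter, a filter of 5 TPM or no trend were not recorded for this gene. Rnu12, the U12 RNA of the same particle, stood at 120.4 ± 18.3 TPM in controls and 99.4 ± 36.0 TPM in mutants (SD, n = 3; log2 difference −0.33, limma adjusted p = 0.52). That difference was −0.06 without mutant replicate 2, −0.22 without control replicate 2 and −0.59 without mutant replicate 1.

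**Figure D1:**
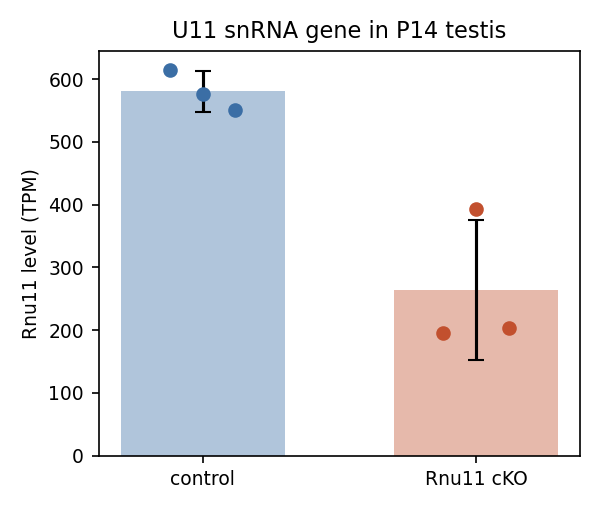
Rnu11 level in TPM (vertical axis) in the 2 genotypes; points are the 3 libraries of a group, bars the mean and error bars the SD. The 3 mutant libraries, at 196 to 393 TPM, lie below the 3 controls, at 550.3 to 614 TPM.

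For minor introns, isoforms that splice the intron were lower relative to those that do not in mutants. For each intron, the TPM of isoforms that splice it was set against the TPM of isoforms of the gene that span its position without splicing it. Of 50 testable introns with the sequence of a minor intron, in 49 genes, 40 had a lower spliced-to-unspliced ratio in mutants (80%), against 47.8% of 9935 other introns. The median log2 change was −0.37 for minor introns and 0.02 for the others, and the median unspliced share of minor introns was 15.3% in controls and 22.9% in mutants. The shift of the set passed limma's camera test (p = 1.4e-12) and also passed it with an estimated correlation (p = 0.011). In 18 minor introns every mutant library was below every control, and in 1 every mutant was above; 38% of minor introns were free of overlap, against 12.3% of other introns and 10% by chance.

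The minor introns with the smallest p-values lie in Rpl4, Ubl5, Prim1, Tmem258 and Exosc2. In Rpl4, which encodes a ribosomal protein, the intron at chromosome 9, 64175301 to 64175583 (+ strand, 5′ splice site GTATCCTT) was unspliced in 3.28% ± 0.46 of the transcript TPM in controls and in 14.3% ± 0.23 in mutants (SD, n = 3). This was the single minor intron called over all introns (log2 ratio change −2.29, SE 0.16, limma adjusted p = 0.036). The call was lost without any 1 of the 6 libraries (adjusted p 0.070 to 0.26). This intron also holds the snoRNA gene Snord16a, which was listed at 0 TPM in all 6 libraries. Among the 9935 other introns 1 was called too, in Pfdn6, with a smaller p-value (log2 ratio change −5.65, limma adjusted p = 6.2e-04). It was unspliced in 88.3% ± 1.80 in controls and in 100% in mutants (SD, n = 3). Adjusted over the minor introns alone, 7 of the 50 were called, all with a lower spliced-to-unspliced ratio in mutants. Besides Rpl4 these lay in Ubl5, a ubiquitin-like protein that itself acts in splicing (unspliced 3.38% ± 0.41 in controls, 9.93% ± 1.62 in mutants; SD, n = 3), and in Prim1, the catalytic subunit of DNA primase (11.3% ± 3.06 and 32.1% ± 3.15). For Ubl5, as for every intron here, unspliced means isoforms that do not splice this exact intron, which need not retain it. In Prim1 another intron, at 128021732 to 128022862, was unspliced in 9.45% ± 1.57 in controls and 28.9% ± 3.01 in mutants (SD, n = 3). Its unspliced isoforms had a mean of 1.8202 TPM, the same value as the isoforms that retain the minor intron whole. Both ratios thus appear to read the same isoforms, so they cannot tell whether the change was particular to the minor intron. Tmem258, a subunit of the oligosaccharyltransferase complex, went from 6.24% ± 0.92 to 13.4% ± 0.96, and the RNA exosome component Exosc2 from 15.2% ± 2.06 to 30.2% ± 2.23. The transcription factor gene E2f6, at 13.1% ± 1.85 in controls and 27.4% ± 3.50 in mutants, and the translocon gene Ssr3, at 5.18% ± 0.13 and 8.51% ± 0.68, completed the 7. The introns of Prim1 and E2f6 start ATATCCTT, those of Ubl5, Tmem258 and Ssr3 GTATCCTT and that of Exosc2 GTATCCTG. On GRCm38 they lie at chromosome 9, 20645660 to 20646615 (Ubl5), chromosome 10, 128022973 to 128023582 (Prim1), chromosome 19, 10206534 to 10207163 (Tmem258), chromosome 2, 31675905 to 31676667 (Exosc2), chromosome 12, 16820385 to 16822092 (E2f6) and chromosome 3, 65382035 to 65382991 (Ssr3). The test covers introns whose bases are contained in an annotated transcript, 8.33% of the introns of protein-coding genes, so introns with an annotated retaining isoform are over-represented.

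**Figure D2:**
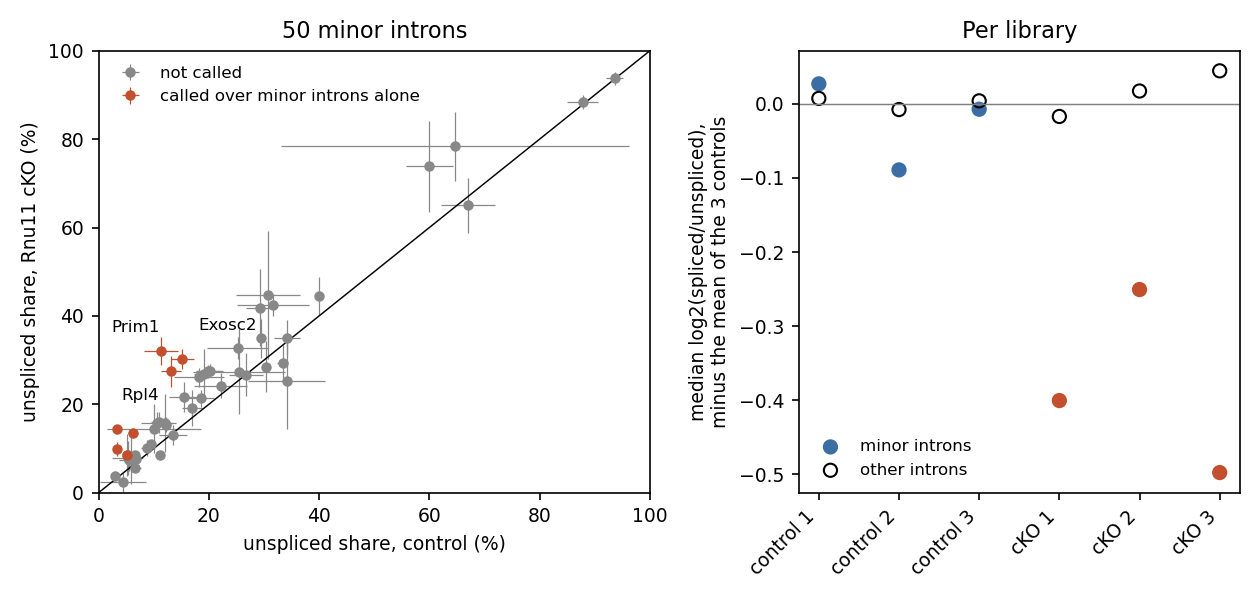
Left, the share of transcript TPM (%) in isoforms that do not splice each of the 50 minor introns, in controls (horizontal) and mutants (vertical), as mean ± SD of 3 libraries, with the line of equal shares. Right, the median log2 ratio of spliced to unspliced isoforms per library relative to the control mean, for minor introns (filled; blue control, orange mutant) and other introns (open). Minor introns lie at −0.25 to −0.50 in mutants and at −0.09 to 0.03 in controls.

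No gene listed as having a minor intron was called by limma at the level of the gene. The hand-written list came from general knowledge, so some of its genes may have no minor intron in mouse. Of its 57 tested genes, 32 were higher and 25 lower in mutants, with a median log2 difference of 0.04 against 0.11 for other protein-coding genes. None was called over all genes or adjusted over the list alone, while 6 higher and 5 lower genes were at an unadjusted p under 0.05. Fisher's exact test of called against not called had no calls to compare, in or outside the list. Of genes at an unadjusted p under 0.05 and lower in mutants, the list held 5 of 57 and other protein-coding genes 515 of 12897 (Fisher's exact test, p = 0.078). This version on unadjusted p-values was not planned. It treats genes as independent, while the estimated correlation within this list was 0.26, so its p-values here and below are likely too small. Only 9 of the 60 genes written have a minor intron among the introns that could be read, so lists from the intron sequence were added after the data were examined. They held 7 such lower genes of 71 (Fisher's exact test, p = 0.023), 6 of 48 with no mismatch at the 5′ splice site (p = 0.012), and 12 of 119 for the hand-written and sequence lists together (p = 0.0030), beside 8, 3 and 13 higher ones. These 3 lists had medians of 0.04 to 0.05 and pointed to lower by camera (p = 0.089, 0.047 and 0.045), a shift that missed the threshold with an estimated correlation (p = 0.61, 0.50 and 0.60) or adjusted with the other lists (adjusted p = 0.13, 0.077 and 0.073). The set test pointed to lower and missed the threshold (camera, adjusted p = 0.16, and 0.76 with an estimated correlation); the median and mean were above 0 because the median gene of the data was at 0.09. After median-ratio scaling or scaling to protein-coding genes, the median became −0.07 or −0.08 and the list was called lower (camera, adjusted p = 0.031 and 0.029; 0.029 to 0.76 over all alternatives). The 6 higher members with the smallest p-values were Tmem161b, Mapk8, Mapk3, Mapk13, Mapk9 and Msh3, at log2 differences of 0.26 to 0.49. The 6 lower ones were E2f1, Kifap3, E2f5, Braf, Actr10 and E2f2, at −0.38 to −0.23. No gene family was tested, and E2f3, E2f4 and E2f6 stood at 0.04 to 0.19. E2f1 stood at 9.79 ± 0.89 TPM in controls and 7.32 ± 0.42 TPM in mutants (SD, n = 3).

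Genes for proteins of the minor spliceosome itself were not called as a list (15 tested, 11 higher; camera, adjusted p = 0.48). Their median log2 difference was 0.12, near the 0.10 of all protein-coding genes, and 0.03 after median-ratio or protein-coding scaling. Adjusted over the list alone, 2 members rose and none fell. Rnpc3, which encodes a protein that bridges U11 and U12, went from 43.6 ± 3.72 to 60.3 ± 3.72 TPM, and Ccdc84, which encodes another minor spliceosome protein, from 15.3 ± 1.69 to 21.4 ± 0.61 TPM (SD, n = 3; log2 difference 0.46 for both; limma, adjusted p = 0.022 over the list alone and 0.29 over all genes). Snrnp25 (log2 difference 0.21) and Pdcd7 (−0.18) were not called. Among 11 spliceosomal and related small RNAs, 6 were higher and 5 lower. The list was not called (camera, adjusted p = 0.14), its test pointed to lower while its median (0.03) and mean (0.14) were above 0, and the median was −0.08 after median-ratio scaling. Over this list alone, Rnu11 and the U1 copy Rnu1b1 fell (limma, adjusted p = 0.029 and 0.046). Rnu1b1 went from 5458 ± 2008 to 2269 ± 825 TPM (SD, n = 3), while the copies Rnu1b6 and Rnu1b2 had log2 differences of 1.88 and 1.14, which ranged from 1.07 (without control replicate 3) to 2.93 (without control replicate 1), and from 0.57 (without mutant replicate 3) to 1.54 (without mutant replicate 2; 0.72 without control replicate 3). These copies are near-identical, so reads can be split between them and their single values are uncertain.

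Genes of meiotic prophase were lower in mutants as a group. Of 42 tested genes of leptotene and zygotene, 39 were lower, with a median log2 difference of −0.38. The list fell by limma's camera test (adjusted p = 1.3e-25), a call lost with an estimated correlation (adjusted p = 0.23). None of its members was called over all genes, 18 were called lower adjusted over the list alone, and in 24 of 42 the groups did not overlap, all of them lower (no overlap in either direction was found in 20.3% of all genes, with 10% expected by chance). Hfm1, a helicase needed for crossover formation, stood at 19.6 ± 1.94 TPM in controls and 9.14 ± 0.20 TPM in mutants (SD, n = 3; log2 difference −1.02, SE 0.10, limma adjusted p = 0.053 over all genes). Smc1b, a meiotic cohesin, went from 39.6 ± 2.06 to 24.3 ± 3.34 TPM, Sycp2, of the synaptonemal complex, from 80.9 ± 9.04 to 51.8 ± 6.74 TPM, and Tex15 from 75.5 ± 4.66 to 54.0 ± 3.47 TPM (SD, n = 3; each called over the list alone). Spo11, which makes the breaks that start recombination, was also among the 18, with a log2 difference of −0.64.

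Other germ cell lists shared this direction, apart from the earliest stage. Of 24 pachytene genes 21 were lower, with a median of −0.61 (camera, adjusted p = 6.3e-07, and 0.40 with an estimated correlation). None of these was called adjusted over the list alone. Adad1 (log2 difference −0.68) and Zpbp (−0.41) were lower, and Ccnb3 (0.54) and Nxf3 (0.63) were higher than every control. Ccnb3 and Nxf3 are X-linked, and sex chromosomes are silenced in pachytene cells, so both may be poor markers of this stage. Control replicate 2 read as low as the mutants here: its mean pachytene level was −0.63 log2 units from the control mean, the other controls were at 0.34 and 0.29, and the mutants were at −0.58, −0.56 and −0.22. Of 22 piRNA pathway genes 21 were lower (median −0.35; camera, adjusted p = 8.6e-11, and 0.23 with an estimated correlation), 7 of them called over the list alone, among them Mael, Mov10l1, Rnf17 and Tdrd9. Mael went from 89.1 ± 7.02 to 64.3 ± 4.95 TPM (SD, n = 3). Here too control replicate 2 read low, with a mean piRNA pathway level of −0.23 against 0.10 and 0.13 in the other controls and −0.37, −0.36 and −0.22 in mutants. Of 13 genes of differentiating spermatogonia 11 were lower, with a median of −0.21 (camera, adjusted p = 7.1e-06, and 0.20 with an estimated correlation). This median was −0.32 after median-ratio and −0.34 after protein-coding scaling. The list's mean difference from other genes ran from −0.32 to −0.15 with 1 library left out. Dmrtb1 (log2 difference −0.47), Dazl (−0.36) and Sohlh2 (−0.36) were among 5 called lower over the list alone, and Ccnd2, a cyclin, was called higher (0.87). Among 4 round spermatid genes above the filter 3 were lower (median −0.13; camera, adjusted p = 0.039, and 0.36 with an estimated correlation), and Odf2l was called over the list alone (−0.43), against Spaca1 at −0.21, Tssk2 at −0.04 and Tssk6 at 0.04. This list had 28 genes written, so most were not tested. Spaca1, Tssk2 and Tssk6 averaged 1.59, 1.16 and 0.99 TPM in controls and Odf2l 22.9 TPM. Such a list cannot tell whether spermatids were present or changed. The round spermatid call was lost after median-ratio or protein-coding scaling (adjusted p = 0.10 and 0.11, with medians of −0.19 and −0.28), and without control replicate 1, mutant replicate 1 or mutant replicate 2 (0.087, 0.065 and 0.13; 0.0065 to 0.36 over all alternatives). Genes of undifferentiated spermatogonia were not called (14 tested, 9 higher, median 0.07; camera, adjusted p = 0.89), and this median was −0.01 after median-ratio scaling and −0.02 after protein-coding scaling. Neurog3 (0.35), Etv5 (0.35), Ret (0.21) and Shisa6 (0.97) had the smallest p-values in that list and missed the threshold; Shisa6 was at 0.43 without mutant replicate 2, 0.61 without control replicate 3 and 1.47 without mutant replicate 3.

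**Figure D3:**
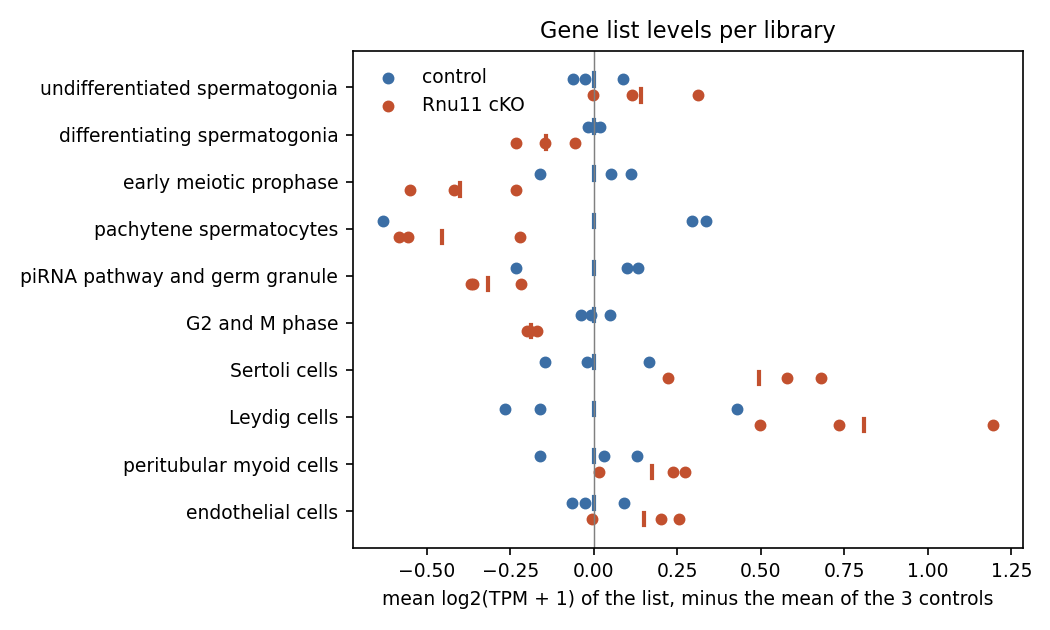
Mean log2(TPM + 1) of 10 gene lists per library, relative to the mean of the 3 controls (horizontal axis, log2 units); points are libraries and vertical marks group means. For early meiotic genes the mutants lie at −0.55 to −0.23 and the controls at −0.16 to 0.11; for pachytene genes control replicate 2, at −0.63, lies with the mutants.

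Sertoli and Leydig cell genes were higher in mutants. Of 28 Sertoli cell genes 27 were higher, with a median log2 difference of 0.48 (camera, adjusted p = 4.4e-09, and 0.39 with an estimated correlation). None was called over all genes, and 12 were called higher over the list alone. They included Clu, a secreted chaperone, at 849 ± 25.8 TPM in controls and 1330.1 ± 190.2 TPM in mutants, and the protease gene Ctsl at 303 ± 35.2 and 461 ± 23.6 TPM (SD, n = 3). Defb36 (log2 difference 0.72) and Mro (0.57) were among them too. All 13 Leydig cell genes were higher, with a median of 0.68 (camera, adjusted p = 0.0016, and 0.45 with an estimated correlation), and 2 were called over the list alone. These were Fdx1, which passes electrons to steroid-forming enzymes (18.1 ± 6.58 to 39.3 ± 6.24 TPM), and Star, which brings cholesterol into mitochondria (7.26 ± 4.16 to 20.4 ± 8.02 TPM; SD, n = 3). Cyp11a1 (1.06) and Cyp17a1 (2.26) were not called. Control replicate 2 stood apart here as well: its mean Leydig level was 0.43, against −0.16 and −0.27 in the other controls and 0.74, 1.19 and 0.50 in mutants, and its Cyp17a1 read 37.0 TPM against 3.88 and 7.50 TPM in the other controls and 39.2 TPM in the lowest mutant. Macrophage genes were called at the edge of the threshold (11 of 13 higher, median 0.38; camera, adjusted p = 0.0496, and 0.72 with an estimated correlation). Csf1r (0.55), C1qc (0.48), C1qb (0.49) and Aif1 (0.54) had the smallest p-values. Control replicate 2 overlapped the mutants, with a mean macrophage level of 0.29 against 0.29, 0.51 and 0.05 in mutants. The macrophage call was lost without control replicate 1 (adjusted p = 0.36), control replicate 3 (0.16), mutant replicate 2 (0.11) or mutant replicate 3 (0.052), and ranged from 0.0062 to 0.72 over all alternatives. Peritubular myoid genes (9 of 11 higher, median 0.24, and 0.13 after either scaling; adjusted p = 0.15), with Tpm2, Smtn, Myl9 and Mylk at 0.26 to 0.34, and endothelial genes (12 of 13 higher, median 0.12, and 0.04 or 0.05 after median-ratio or protein-coding scaling; adjusted p = 0.32), with Pecam1, Ptprb, Cdh5 and Tie1 at 0.21 to 0.31, were not called. Blood and adjoining tissue gave 2 genes above the filter each, too few for a set test. Hbb-bs, an adult globin, went from 4.07 ± 0.75 to 10.8 ± 4.76 TPM and Alas2 from 7.18 ± 1.18 to 10.5 ± 1.52 TPM, both above every control, while Plin1 and Cst11 overlapped between the groups (SD, n = 3).

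Proliferation genes were lower and early response genes higher. Of 25 S phase genes 22 were lower (median −0.17; camera, adjusted p = 1.1e-07, and 0.19 with an estimated correlation), with Uhrf1 at −0.37, Gins1 at −0.45, Rrm2 at −0.28 and Mcm7 at −0.20 and none called over the list alone. Of 24 G2 and M phase genes 21 were lower, with a median of −0.20 (camera, adjusted p = 2.2e-10, and 0.078 with an estimated correlation). Cdc20 (−0.44) and Aurka (−0.36) were called over the list alone, and Ccnb2 (−0.38) and Kif20a (−0.27) were not. After median-ratio and protein-coding scaling the median was −0.28 and −0.30 for S phase genes, and −0.30 and −0.32 for G2 and M phase genes. Of 16 immediate early and stress genes 14 were higher (median 0.45; camera, adjusted p = 2.7e-04, and 0.23 with an estimated correlation). Over the list alone 7 were called higher, among them the transcription factor genes Junb (4.65 ± 0.21 to 7.88 ± 0.59 TPM; SD, n = 3), Jun (log2 difference 0.47) and Atf3 (0.44), and Ier2 (0.51). All 13 integrated stress response genes were higher (median 0.25; camera, adjusted p = 0.018, and 0.54 with an estimated correlation), with the smallest p-values for Sesn2 (0.45), Ddit3 (0.25), Phgdh (0.36) and Atf4 (0.25), none of them called over the list alone. That call was lost without control replicate 1 (adjusted p = 0.12; 2.3e-04 to 0.54 over all alternatives). The stress response median was 0.15 after median-ratio and 0.16 after protein-coding scaling, and control replicate 2 (mean level 0.17) lay above mutant replicate 3 (0.12). Targets of p53 were not called (21 of 25 higher, median 0.15, and 0.04 after either scaling; adjusted p = 0.32), with Ddit4 at 0.46, Btg2 at 0.49 and Ckap2 at −0.23. In all, 12 of 21 testable lists were called by camera with a preset correlation, 7 lower and 5 higher. None was called with an estimated correlation, and 2, the G2 and M phase list and the immediate early list, by limma's fry test (adjusted p = 0.044 and 0.047).

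Over all 17959 genes tested, limma called 5, of which 1 was higher and 4 were lower in mutants, and no protein-coding gene passed. At an unadjusted p under 0.05 there were 2890 genes (16.1%), 2176 of them higher, with 898 expected by chance. The median gene stood at a log2 difference of 0.09, so the tilt to higher can include a shift of the whole TPM scale. The chance count also takes genes as independent. Libraries of the groups did not overlap in 3640 genes, 20.3% against 10% by chance. The split of calls was 0 higher and 3 lower after median-ratio scaling, and 1 higher and 3 lower after protein-coding scaling; without control replicate 3 there were 9 calls. The called genes were a processed pseudogene, Gm7432, and 4 short RNA genes. Gm7432 stood at 3.42 ± 0.15 TPM in controls and 19.3 ± 5.90 TPM in mutants (SD, n = 3; adjusted p = 0.036), and as a pseudogene it can share reads with its parent gene. The snRNA gene Gm25556, which falls outside the rule for named genes and was chosen after its values were seen, went from 21.9 ± 1.44 to 8.71 ± 0.94 TPM (SD, n = 3; adjusted p = 0.036). Gm44349, an annotated miRNA gene, was listed at 0 in all mutants and at 5.91, 9.77 and 8.03 TPM in controls. The snRNA gene Gm22042 was listed at 0 in mutants and at 5.56, 9.52 and 13.0 TPM in controls, and the snoRNA gene Gm22300 at 0 in mutants and at 3.94, 7.81 and 8.03 TPM in controls. Gm44349 stayed called when any 1 library was left out; Gm22042 was called in 2 of the 6 such fits, Gm22300 and Gm7432 in 1 each, and Gm25556 in none. Of protein-coding genes with a mean of at least 5 TPM and no overlap, those with the smallest p-values missed the threshold: Hfm1, Gm10184, Pde6d and Boll were lower (log2 differences −1.02, −0.82, −0.73 and −0.63), and 4930486L24Rik, Odr4, Dusp3, Unc45a, Erbb4 and Junb higher (0.65 to 1.24), at adjusted p of 0.053 to 0.27 (limma). Hfm1 passed in at least 1 alternative (limma, adjusted p 0.028 to 0.22 over all alternatives). Boll is a germ cell translation regulator and Erbb4 a receptor tyrosine kinase.

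At the level of isoforms, 6 of 44197 were called (limma), 2 higher and 4 lower, and 4966 (11.2%) were at an unadjusted p under 0.05. An Rpl4 isoform annotated as retaining an intron, ENSMUST00000217055, rose from 5.48 ± 0.62 to 28.6 ± 3.01 TPM (SD, n = 3; adjusted p = 0.0055). The isoform ENSMUST00000108369 of Ltbp4, which encodes a TGF-beta binding matrix protein, rose from 0.93 ± 0.13 to 11.9 ± 2.35 TPM (SD, n = 3; adjusted p = 0.0055). The lower calls were listed at 0 in all mutants. They were an Mrps12 isoform at 5.38, 6.22 and 5.46 TPM in controls, a Pfdn6 isoform at 4.19, 5.31 and 4.27 TPM, and the single isoforms of Gm44349 and Gm22042. Among 35607 isoform shares 4 were called, 1 higher and 3 lower, with 2059 (5.78%) at an unadjusted p under 0.05. The Ltbp4 isoform made up 1.29% ± 0.10 of its gene in controls and 12.03% ± 1.29 in mutants (SD, n = 3; adjusted p = 0.012). The Mrps12, Pfdn6 and Egfl7 isoforms made up 20.8% ± 1.90, 11.7% ± 1.80 and 12.9% ± 0.95 in controls (SD, n = 3) and were listed at 0 in mutants. The Rpl4 retaining isoform, from 3.11% ± 0.43 to 13.5% ± 0.16 (SD, n = 3), missed the threshold for shares (adjusted p = 0.052). Both counts depend on single libraries: 11, 10, 10 and 3 isoforms were called without control replicate 1, control replicate 2, mutant replicate 2 and mutant replicate 3, and 2, 1 and 10 shares without control replicate 1, control replicate 2 and mutant replicate 1.

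X-linked genes stood slightly above autosomal ones. The median log2 difference was 0.17 over 689 X-linked genes, of which 74.6% were higher in mutants, and 0.09 over 17090 autosomal genes, of which 66.2% were higher. Sex chromosomes are silenced in pachytene cells. The X-linked set passed the camera test (p = 0.021) and missed it with an estimated correlation (p = 0.61), with no expression filter (p = 0.18), and without control replicate 1 (p = 0.058), control replicate 3 (p = 0.075) or mutant replicate 3 (p = 0.081). Y-linked genes (9 tested, 4 higher, median −0.01, mean 0.01; camera, adjusted p = 0.55), with Uty at 0.36, Kdm5d at 0.23, Ddx3y at 0.24 and Usp9y at −0.17, were not called. Nor were mitochondrially encoded mRNAs (13 tested, 8 higher, median 0.11, mean −0.03; camera, adjusted p = 0.77), with mt-Nd1 at 0.27, mt-Nd2 and mt-Co1 at 0.20 and mt-Nd5 at 0.17; their median was 0.00 after median-ratio scaling.

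The authors' deposited table gives a confident log2 fold change for each gene, and 27607 genes have one other than 0. Among the genes tested here it lists 199 at or above 1 and 220 at or below −1, of which 73 and 64 are protein-coding. Of these 419 genes limma called 5 and placed 234 at an unadjusted p under 0.05. The 419 include Gm22042, Gm44349 and Gm22300, listed there at −100 with an average of 0 TPM in mutants. A value of −100 is not a measured fold change. Where the authors' deposited table gives a value other than 0 to a tested gene, its sign matched the limma fit in 96.1% of 16227 genes. For Rnu11 the authors' deposited table lists −1.29 and for Hfm1 −1.10.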

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

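Added after the results were seen were the motif lists, the ratio with an estimated correlation, and the ratios of retained isoforms and of introns without small RNA genes. Genes called (5) became 8 with a pseudocount of 0.1, 3 after median-ratio scaling, 0 with no filter, 3 with a filter of 5 TPM, 3 without trend and 0 with a replicate block; without 1 library they were 4 to 9. With this block, isoforms called (6), shares called (4) and minor introns called over all introns (1) were each 0. Isoforms were 11 with a pseudocount of 0.1 and 3 to 11 without 1 library; shares were 1 to 10 without 1 library. Minor introns called over all introns were 0 among those with no small RNA gene and 0 to 0 without 1 library. With an estimated correlation, lists called went from 12 to 0, with mean differences from other genes of −0.48 for early meiotic genes, −0.53 for pachytene, 0.41 for Sertoli, 0.73 for Leydig and 0.082 for X-linked genes. The X-linked difference was 0.016 with no filter and 0.066 to 0.107 without 1 library. The minor intron gene set stood at −0.066 after median-ratio and −0.071 after protein-coding scaling, both past the threshold. Rnu11 ranged from −1.53 to −1.03 without 1 library. The minor intron ratio (median −0.37) kept its direction and passed camera in each alternative run, at −0.48 to −0.31 without 1 library. Of 1383 alternatives for 108 single genes, 36 were weaker and 2 stronger; of 53 for introns 7 were weaker; of 85 for isoforms and shares 23 were weaker and 1 stronger; of 223 for other lists 20 were weaker and 4 stronger. Only a result called in the main fit could become weaker or be reversed. The weaker cases of genes all fall on the 5 called genes, and those of introns all on the Rpl4 intron. Most of the alternatives for genes and introns could therefore not weaken, and the calls were less stable than these totals make them look. No called direction was reversed. The sign of a value changed in 3 of the alternatives for genes and 4 of those for lists. The causes were not tested. TPM keeps no depth, so what depth limits is unknown.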

Other observations

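Among 15 introns of 6 genes of the minor spliceosome, picked after the results were seen, none was called over all introns by limma, and 7 were at an unadjusted p under 0.05. These 7 are not independent: 2 Snrnp48 introns had identical values, and 2 Rnpc3 introns share a 5′ splice site and mirror each other. Adjustment over these 15 alone favours what had been seen, so the values below are leads to test elsewhere. In Rnpc3, the intron at chromosome 3, 113607300 to 113608339, was unspliced in 56.9% ± 3.44 of the transcript TPM in controls and in 86.2% ± 2.05 in mutants. The alternative Rnpc3 intron with the same 5′ splice site, 113605648 to 113608339, went from 41.9% ± 7.79 to 13.1% ± 1.41 unspliced (SD, n = 3; limma, adjusted p = 3.9e-04 and 0.0010 over these 15 introns, 0.088 and 0.17 over all introns). In Snrnp48, the intron at chromosome 13, 38211142 to 38216324, went from 80.7% ± 3.14 to 60.6% ± 2.83 unspliced (SD, n = 3; limma, adjusted p = 0.0017 over these introns, 0.26 over all). In Ccdc84, 2 introns were called over these introns alone (limma, adjusted p = 0.032 and 0.040) and had an adjusted p of 0.79 over all. As background, U11 particles are known to bind an element in Rnpc3 and Snrnp48 transcripts that steers their splicing; no test here addresses that element.

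When only isoforms that retain the whole intron were set against the spliced ones, a test added after the results were seen, 38 of 44 minor introns had a lower ratio in mutants (median log2 change −0.45). Over these introns alone 9 were called (limma), in Rpl4, Prim1, Tmem258, E2f6, Exosc2, Ssr3, Derl2 (2 introns) and Rmc1. In Derl2, which acts in the clearance of misfolded proteins, the intron at chromosome 11, 71014644 to 71015726, went from 16.9% ± 1.11 to 27.5% ± 1.48 retained. In Rmc1 the share went from 10.8% ± 2.12 to 19.3% ± 0.93 (SD, n = 3), but against all isoforms that do not splice it the same intron went the other way, from 34.1% ± 7.04 to 25.2% ± 10.87 unspliced (log2 ratio change 0.63, not called). The Ubl5 intron was not in this test, since isoforms that retain it whole were below the filter. In the 30 genes with both kinds of intron tested, a look also added after the results were seen, 93 other introns had a median change of −0.01 (48 lower) and 31 minor introns one of −0.26 (23 lower).

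Of the tests below, those on cell mix and scaling, and that on small RNA genes inside introns, were chosen or reworded after the results were seen. Meiotic genes were lower while Sertoli and Leydig cell genes were higher. Scaling by abundant short RNAs moves all genes of a library the same way, and these lists moved in opposite directions. That argues against scaling as the whole cause. Rescaling could not have removed both shifts, so its outcome adds description only. After it no library overlapped between groups. The Sertoli score stood 0.39 log2 units higher in mutants after median-ratio scaling (SD 0.13 in controls, 0.14 in mutants, n = 3) and 0.40 after protein-coding scaling. The early meiotic difference grew from −0.40 to −0.50 (SD 0.18 and 0.25, 1.97 times the larger SD) and −0.54. Fewer germ cells of every kind would leave the score of undifferentiated spermatogonia minus the early meiotic score alike in both groups. It differed by 0.54 (SD 0.22 and 0.32), but control replicate 2 (0.25) overlapped mutant replicate 3 (0.23), so this cause could still contribute. More somatic cells of every kind would leave Sertoli and Leydig scores minus myoid and endothelial scores alike. This score was 0.49 higher in mutants (SD 0.25 and 0.19), which leans against that cause. The difference was narrowly under 2 SD of the controls, the bound set, so a contribution is not excluded. No library overlapped between the groups in this score, with controls at −0.26 to 0.24 and mutants at 0.35 to 0.70. A delay or loss of meiotic cells in mutants stays open as a hypothesis that was not tested here. The cells in which Rnu11 was deleted are not given.

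The ratio of spliced to unspliced isoforms was lower for minor introns. More unspliced RNA of all genes would lower other introns too, but of 10000 draws of other introns matched on TPM and unspliced share, 0 had a median as low as −0.37 (lowest draw −0.20). The draws take introns as independent and do not measure the spread between animals. For the minor introns, another split of the 6 libraries gave a median of size 0.28, larger than the lowest draw. Of the 50 minor introns 49 hold no small RNA gene, and these had a median of −0.37, with 79.6% lower. Small RNA genes inside introns thus do not account for the shift of the set. Leaving out 1 intron could hardly have moved the median. For the Rpl4 intron, which holds such a gene, the question stays open. A change of cell mix stays open: 1 control, replicate 2, had a pachytene score as low as those of the mutants (−0.63, below their lowest of −0.58), and its minor intron median (−0.09) lay above those of the mutants (−0.25 to −0.50), but a single library decides nothing. Reduced minor splicing after loss of U11 is a hypothesis that these tests leave standing.

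Of 537 short RNA genes tested, 5 were listed at 0 in all mutants and above 0 in all controls, and 2 the other way round. Estimates that drop to 0 without a change of the RNA could account for these, since 310 of the 537 were at 0 in at least 1 library, and neither count decides it.

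The 6 libraries can be split into 3 and 3 in 10 ways, and the splits are too few for a share under 0.05. Each count of splits as large includes the real split, so a count of 1 means that no other split was as large. The real split gave 5 genes called and the highest other 11, with 3 splits as large; for lists the values were 12 and 12 (2 splits), and for isoforms 6 and 12 (3 splits). The split with 11 genes set control 1, control 2 and mutant 1 against the rest. For isoform shares the real value was 4 and the highest other 3, for the size of the minor intron median 0.37 and 0.28, for minor introns called over themselves 7 and 0, for the size of the minor intron gene difference 0.056 and 0.043, and for the X-linked difference 0.0822 and 0.0752, each with 1 split as large. On the first principal component (33.7% of the variance) controls lay at −31.9, −0.32 and −30.5 and mutants at 17.9, 45.7 and −0.90, so control replicate 2 and mutant replicate 3 lay together.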
